A study of Rattus norvegicus with 25 samples.

How the data were processed

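RNA was taken from the ipsilateral striatum of 25 rats, each giving 1 library, and polyadenylated RNA was sequenced. The authors deposited 1 table of raw read counts with 28909 gene names and 25 libraries. Reads were checked with FastQC, aligned with STAR and counted per gene with HTSeq on the Rnor_6.0 build, per the submitters' processing notes. Versions, annotation release, strand setting and any read filter were not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and near-identical gene copies are uncertain. All gene names were kept as deposited; 17131 of them matched a symbol and 18993 a symbol or synonym in a RefSeq table of the GRCr8 assembly. An Rnor_6.0 annotation was not used here, so no coordinates are given. In 9462 table lines every library had a count of 0.

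Each library's arm was read from its label. Total counts were summed per library over all genes and ran from 10838513 to 20532290. Libraries of an arm were taken as separate animals, since the labels describe randomised animals, though they do not say so library by library. No pair of libraries of the same arm agreed within sampling noise. Over genes with at least 20 reads the lowest chi-square per degree of freedom was 12.0, 4.92 and 4.83 in the levodopa, 7.5 mg/kg and 15 mg/kg arms. Pairs of libraries from different arms were not compared in this way. No batch, date or surgery order was given in the sources used here, so no value within batches can be given. Behavioural scores named in the labels were not analysed here.

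Genes were kept by edgeR's filterByExpr with the arm as group, which left 14142. Library sizes were scaled by TMM, and edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) was fitted to all 25 libraries with arm as the 1 factor (common biological coefficient of variation 0.139). All 4 contrasts were taken from that fit: each dose against levodopa, the doses against each other, and the mean of both doses against levodopa. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Every adjusted p of a gene is from this edgeR test unless another tool is named. Errors of log2 fold changes are standard errors, computed as the fold change over the square root of the quasi-likelihood F. CPM values are the deposited counts scaled to a common library total with edgeR's cpm function and the TMM factors. A library was counted in a direction when its log2 CPM, with a pseudocount of 2, lay on that side of the reference arm's mean. Such a count leaves out the spread of the reference arm, so it does not show that the ranges of the arms were separate.

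Gene lists were tested with camera (edgeR and limma) with the correlation between genes estimated from the data, adjusted over the lists within a comparison. Of 36 lists, 35 had the minimum of 5 tested members. Camera with a preset correlation of 0.01 and fry were alternatives; of the lists called with the preset correlation, the MAP kinase feedback list between the doses was the 1 that also held with an estimated correlation. Counts adjusted over the list alone used Benjamini-Hochberg adjustment within the list. A list score is the mean over members of z-scored log2 CPM. Lists, comparisons, tests and the rule for named genes were fixed before the data were examined. The rule took, per comparison, up to 10 called genes with the smallest p in each direction, with a mean of at least 1 CPM and no placeholder name. It added up to 4 called members of each list, or the member with the smallest p, and a set of dopamine, neuropeptide, activity and growth factor genes whatever their result. Genes outside that rule are named as chosen after their values were seen.

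Simulated counts were drawn for each gene independently, from the means and spreads per gene and the library sizes of all 25 libraries. The same steps were tested on them for 15 mg/kg against levodopa, over 14059 genes. They recovered 49 of 67 genes changed 1.5-fold (73.1%), 55 of 66 changed 2-fold (83.3%) and 64 of 65 changed 4-fold (98.5%), with 12 false calls among 183 (6.56%). A list shifted by -0.3 on the log2 scale was called by camera (adjusted p = 7.56e-05) and 0 of the other lists among 35 were. Members of the simulated list were independent, unlike those of the real lists. The call therefore does not show that such a shift would be found in the real data, and a list that did not pass there is not shown to be unchanged.

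Alternatives changed the normalization (RLE, upper quartile), the low-count filter, the threshold (0.10), the libraries in the fit, the tool (DESeq2, limma-voom with quality weights), the covariates (2 surrogate variables from svaseq, the cortical score, the replicate number as a block) and left out each library in turn. Leaving out levodopa replicate 2 and the 7.5 mg/kg replicate 1 together, adding 4 scores (cortical, pallidal to hypothalamic, choroid plexus and ependymal lists) to the design, and adding the side of the first principal component (2 groups of libraries by k-means) as a block, were added after the data had been seen. Each contrast was also refitted on random regroupings of the libraries, 100 in all with the real one. Intervals of list medians are 95% bootstrap intervals from 2000 resamples of members, which are not independent. Work was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0, and in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.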

Results

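Striatal gene expression was measured by RNA sequencing in 25 female Sprague Dawley rats with a 6-hydroxydopamine lesion, a toxin lesion of the dopamine system used as a model of Parkinson's disease. Per the labels, lesioned animals were randomised to levodopa at 6 mg/kg QD alone (n = 5) or to the same levodopa with trapidil at 7.5 mg/kg BID (n = 10) or at 15 mg/kg BID (n = 10). The animals were dosed for 14 days and the ipsilateral striatum was collected on day 15. The labels tie collection to 1 hour of dosing without saying whether before or after. Trapidil is known as an antagonist of platelet-derived growth factor and as a phosphodiesterase inhibitor. Total gene counts per library ran from 16535828 to 19274429 in the levodopa arm, with a median of 17572135. They ran from 10838513 to 18794463 (median 16617608) in the 7.5 mg/kg arm and from 13862132 to 20532290 (median 18792032) in the 15 mg/kg arm. Mitochondrially encoded genes took 11.7 ± 3.67% (SD, n = 5), 12.1 ± 1.74% (SD, n = 10) and 12.2 ± 0.739% (SD, n = 10) of the counts. Levodopa replicate 2 had the highest mitochondrial share, 17.3%, and the 7.5 mg/kg replicate 1 the lowest total, 10838513.

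The first comparison asked which striatal transcripts differed between trapidil at 7.5 mg/kg and levodopa alone. Ppp1r15a, which encodes a phosphatase subunit that acts on translation factor eIF2α during stress, fell from 64.4 ± 19.5 CPM (library-scaled counts; SD, n = 5) to 33.1 ± 4.80 CPM (SD, n = 10). Its log2 fold change was -0.96 ± 0.12 (SE; edgeR adjusted p = 0.00033; lower in 10 of 10 libraries than the levodopa mean). The fit pooled the spread of all arms although the levodopa animals varied more, so this error and adjusted p can be too small. Dusp2 and Dusp6, which encode phosphatases of MAP kinases, fell with log2 fold changes of -1.65 ± 0.27 (adjusted p = 0.0129; 10 of 10 libraries) and -0.91 ± 0.17 (adjusted p = 0.0428; 10 of 10 libraries). Btg2, an antiproliferative gene of the immediate early class, fell by 1.33 ± 0.25 on the log2 scale (adjusted p = 0.0428; 9 of 10 libraries). These 4 genes were all that passed among 14142 tested, and 0 genes passed in the higher direction with edgeR. At an unadjusted p below 0.05 there were 710 higher and 939 lower genes, where chance alone would give 707.1 in both directions together. DESeq2 called 8 genes higher and limma-voom 19.

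**Figure D1:**
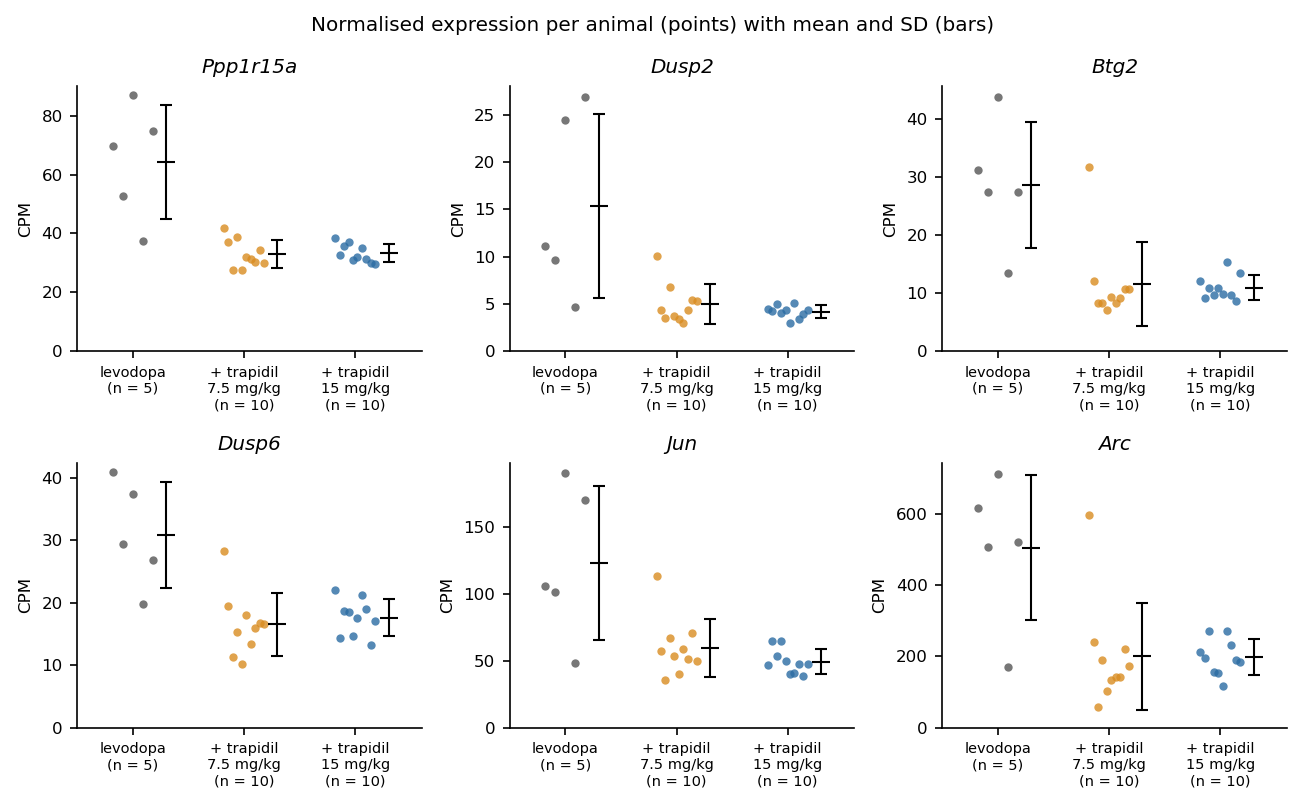
Library-scaled counts in CPM (vertical axes) of Ppp1r15a, Dusp2, Btg2, Dusp6, Jun and Arc in each animal of the 3 arms (points), with the arm mean ± SD. Mean Ppp1r15a was 64.4 CPM with levodopa alone, 33.1 CPM with trapidil at 7.5 mg/kg and 33.3 CPM at 15 mg/kg.

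Immediate early genes, which neurons and other cells transcribe within minutes of stimulation, had a median log2 fold change of -0.55 over 35 members at 7.5 mg/kg, with 29 negative. Of these, 2 fell, Btg2 and Dusp6, and 20 were lower when adjusted over the list alone. Arc, a synaptic plasticity gene of this class, was at 505 ± 204 CPM (SD, n = 5) with levodopa and 200 ± 150 CPM (SD, n = 10) at 7.5 mg/kg, a log2 fold change of -1.34 ± 0.33 that did not pass (adjusted p = 0.135; 9 of 10 libraries). Fos, at -1.43 ± 0.41, did not pass either (adjusted p = 0.2; 9 of 10 libraries). The list test gave adjusted p = 0.161 with an estimated correlation, the list score being lower than the levodopa mean in 9 of 10 libraries.

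Striatal interneuron markers had a median of -0.21 over 14 members and the same adjusted p = 0.161 with an estimated correlation (10 of 10 libraries lower). With edgeR 0 members passed, 2 were lower when adjusted over the list alone, and Zic4 came nearest at -0.63 ± 0.20. Endothelial markers had a median of -0.36 with 15 of 15 members negative. Again 0 passed, 11 were lower when adjusted over the list alone, and the list gave adjusted p = 0.246 with an estimated correlation (10 of 10 libraries lower). That tally leaned on levodopa replicate 2, which scored 3.09 against an arm mean of 0.91, while the highest 7.5 mg/kg animal scored 0.82.

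By camera with an estimated correlation, 0 of 35 lists passed at 7.5 mg/kg. There were 5 lists at an unadjusted p below 0.05, 17 with the preset correlation and 2 with fry. Leaving out 1 library moved the count of 4 genes to 9 without levodopa replicate 2, 1 without replicate 3 or 5 and 33 without replicate 4. It moved to 70 without the 7.5 mg/kg replicate 1, 11 without the 7.5 mg/kg replicate 6, and 2 without any 1 of the 7.5 mg/kg replicates 2 to 5 and 7 to 10. Ppp1r15a was called in every one of these fits, with log2 fold changes between -1.10 and -0.83. Dusp2 lost its call without levodopa replicate 3 (-1.42) or 5 (-1.34). Btg2 and Dusp6 lost theirs without levodopa replicate 1 (-1.30 and -0.78), 3 (-1.13 and -0.83) or 5 (-1.35 and -0.95). They also lost them without any 1 of the 7.5 mg/kg replicates 2 to 5 and 7 to 10, with values between -1.34 and -1.27 for Btg2 and between -0.94 and -0.85 for Dusp6. The list count of 0 became 2 without levodopa replicate 2 and 1 without the 7.5 mg/kg replicate 1. The side of the first principal component, low in levodopa replicates 1, 2, 3 and 5 and the 7.5 mg/kg replicates 1 and 6, was also put in the design as a block. With it 0 genes passed with edgeR, against 703 higher and 778 lower at an unadjusted p below 0.05. Ppp1r15a was then at -0.67 ± 0.14, Dusp2 at -0.95 ± 0.34, Btg2 at -0.63 and Dusp6 at -0.49 ± 0.17, all nearer 0 than without the block. With the replicate number as a block all 4 calls ended too: Ppp1r15a was at -0.87 ± 0.15 (adjusted p = 0.0939), Dusp2 at -1.40 ± 0.34, Btg2 at -1.31 ± 0.25 and Dusp6 at -0.90 ± 0.16. The numbers did not pair the animals, and numbers 6 to 10 held no levodopa animal. This loss therefore cannot tell a weak effect from a poor block. Dusp2, Btg2 and Dusp6, but not Ppp1r15a, also lost their calls with only the 2 arms in the fit (-1.65 ± 0.33, -1.33 ± 0.29 and -0.91 ± 0.19), with the cortical score in the design (-1.46 ± 0.28, -1.23 ± 0.25 and -0.87 ± 0.18) and with the 4 region scores (-1.24 ± 0.28, -0.98 ± 0.24 and -0.66 ± 0.19).

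The second comparison set trapidil at 15 mg/kg against levodopa alone. Ppp1r15a was at 33.3 ± 3.08 CPM (SD, n = 10), a log2 fold change of -0.95 ± 0.12 (edgeR adjusted p = 0.00038). Dusp2 fell from 15.4 ± 9.73 CPM (SD, n = 5) to 4.19 ± 0.658 CPM (SD, n = 10), a log2 fold change of -1.88 ± 0.27 (adjusted p = 0.00093). Aplnr, the receptor of the peptide apelin, fell by 1.20 ± 0.17 (adjusted p = 0.00093), from 5.04 ± 1.51 CPM to 2.19 ± 0.412 CPM. Jun, a subunit of the AP-1 transcription factor, fell from 123 ± 57.4 CPM to 49.5 ± 9.47 CPM, with a log2 fold change of -1.32 ± 0.22 (adjusted p = 0.00751). Syt13, a member of the synaptotagmin family, rose from 145 ± 4.81 CPM (SD, n = 5) to 181 ± 12.2 CPM (SD, n = 10), a log2 fold change of 0.33 ± 0.06 (adjusted p = 0.00928). Each of these 5 genes was on its side of the levodopa mean in 10 of 10 libraries. That tally leaves out the spread of the levodopa animals. The lowest levodopa animal lay below the highest 15 mg/kg animal for Ppp1r15a (37.47 against 38.53 CPM) and Dusp2 (4.70 against 5.14 CPM). The same held for Jun (48.45 against 65.07 CPM), while the ranges of Aplnr and Syt13 did not overlap. Jun lost its call without levodopa replicate 3 (-1.11).

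In all, 185 genes passed at 15 mg/kg, 142 lower and 43 higher, and 7 of them had placeholder names. At an unadjusted p below 0.05 there were 1168 higher and 1589 lower genes. Among the further lower genes were Trim59 (-0.65 ± 0.10), Smad7, an inhibitor of TGF-beta signalling (-0.46 ± 0.08), and Btg2 (-1.39 ± 0.25). Tspan2 (-0.60 ± 0.11), Sema4c (-0.39 ± 0.07) and Stard9 (-0.58 ± 0.11) fell too, all 6 with adjusted p from 0.00363 to 0.0146. Among the higher genes were Mchr1, the receptor of melanin-concentrating hormone (0.55 ± 0.11), Banp (0.32 ± 0.07), Frmd6 (0.57 ± 0.12) and Tmem132e (0.63 ± 0.13). The retinol dehydrogenase Rdh10 (0.50 ± 0.11), the cation channel Trpc7 (0.57 ± 0.12) and Tmem107 (0.51 ± 0.11) rose too, all 7 with adjusted p from 0.0217 to 0.0247. All 13 of these genes were on their side of the levodopa mean in 10 of 10 libraries. Trim59 was called in every fit that left out 1 library, while Smad7 (-0.43) and Btg2 (-1.18) lost their calls without levodopa replicate 3. The other 10 lost theirs without levodopa replicate 2 and without replicate 3: Tspan2 (-0.49 and -0.56), Sema4c (-0.32 and -0.39), Stard9 (-0.49 and -0.55), Mchr1 (0.49 and 0.56), Banp (0.32 and 0.32), Frmd6 (0.47 and 0.61), Tmem132e (0.67 and 0.59), Rdh10 (0.42 and 0.48), Trpc7 (0.45 and 0.59) and Tmem107 (0.52 and 0.43). All 4 genes called at 7.5 mg/kg were among the 142 lower genes at 15 mg/kg, where independent lists would share 0.0402. That number leaves out that both comparisons used the same 5 levodopa libraries. In 100 simulated sets with no effect that sharing by itself gave 0 shared calls. The simulated genes were drawn independently and without a structure of the samples, so neither number is a fair yardstick.

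Of the 35 immediate early genes, 6 fell at 15 mg/kg with edgeR. Adjusted over the list alone, 16 were lower and 4 higher. Besides Jun and Btg2, Dusp6 fell by 0.81 ± 0.17 and Csrnp1 had a log2 fold change of -0.61 ± 0.13 (both adjusted p = 0.0217; 10 of 10 libraries). Arc fell to 198 ± 50.0 CPM, a log2 fold change of -1.35 ± 0.33 (adjusted p = 0.0414; 10 of 10 libraries). Fos, at -1.32 ± 0.41 (adjusted p = 0.0799; 10 of 10 libraries), and Fosb, at 0.61 ± 0.21 (adjusted p = 0.106; higher in 9 of 10 libraries), did not pass and differed in sign. The list median was -0.38 and its adjusted p = 0.483 with an estimated correlation (10 of 10 libraries lower). Jun and Btg2 lost their calls without levodopa replicate 3 (-1.11 and -1.18), Dusp6 without levodopa replicate 1 (-0.68), 2 (-0.82) or 3 (-0.73), and Csrnp1 without levodopa replicate 2 (-0.61) or 3 (-0.62). Arc, which stood at 170.7 CPM in levodopa replicate 4 and at 506 to 710 CPM in the other levodopa animals, lost its call without levodopa replicate 1 (-1.27), 2 (-1.35), 3 (-1.20) or 5 (-1.34). It also lost it without any 1 of the 15 mg/kg replicates 1 to 3 and 5 to 10, with values between -1.41 and -1.29.

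Oligodendrocyte genes, most of them for myelin proteins, were lower at 15 mg/kg in 19 of 19 members, with a median log2 fold change of -0.59. Of these, 7 fell, among them Opalin (-0.74 ± 0.16; adjusted p = 0.0217), Ermn (-0.58 ± 0.13; adjusted p = 0.0298), Mal (-0.56 ± 0.13; adjusted p = 0.03) and Cnp (-0.69 ± 0.17; adjusted p = 0.0382), each lower in 10 of 10 libraries. Adjusted over the list alone, 18 were lower. Opalin was at 192 ± 40.3 CPM with levodopa (SD, n = 5), 130 ± 31.6 CPM at 7.5 mg/kg and 115 ± 25.9 CPM at 15 mg/kg (SD, n = 10 each). The list gave adjusted p = 0.483 with an estimated correlation (9 of 10 libraries lower). Ciliated ependymal cell markers moved the other way over the same arms, with a median of 1.13 over 12 members, 11 of them positive. With edgeR 0 passed, 0 were higher when adjusted over the list alone, and the list also gave adjusted p = 0.483 with an estimated correlation (10 of 10 libraries higher). Oligodendrocyte precursor markers had a median of -0.38 over 13 members. Sox10, a transcription factor of the oligodendrocyte lineage, fell by 0.63 ± 0.16 (adjusted p = 0.0464; 10 of 10 libraries), and 5 members were lower when adjusted over the list alone. Opalin lost its call without levodopa replicate 2 (-0.60) or 3 (-0.72), and Ermn without levodopa replicate 2 (-0.53) or 3 (-0.54) or the 15 mg/kg replicate 3, 6, 7 or 9 (-0.56 to -0.55). Mal lost its call without levodopa replicate 1 (-0.52), 2 (-0.50) or 3 (-0.54) or the 15 mg/kg replicate 3, 6 or 9 (-0.54 to -0.53). Cnp and Sox10 lost theirs without levodopa replicate 1 (-0.68 and -0.59), 2 (-0.55 and -0.54) or 3 (-0.69 and -0.64). They also lost them without any 1 of the 15 mg/kg replicates 1 to 3 and 6 to 10, with values between -0.70 and -0.66 for Cnp and between -0.64 and -0.58 for Sox10.

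**Figure D2:**
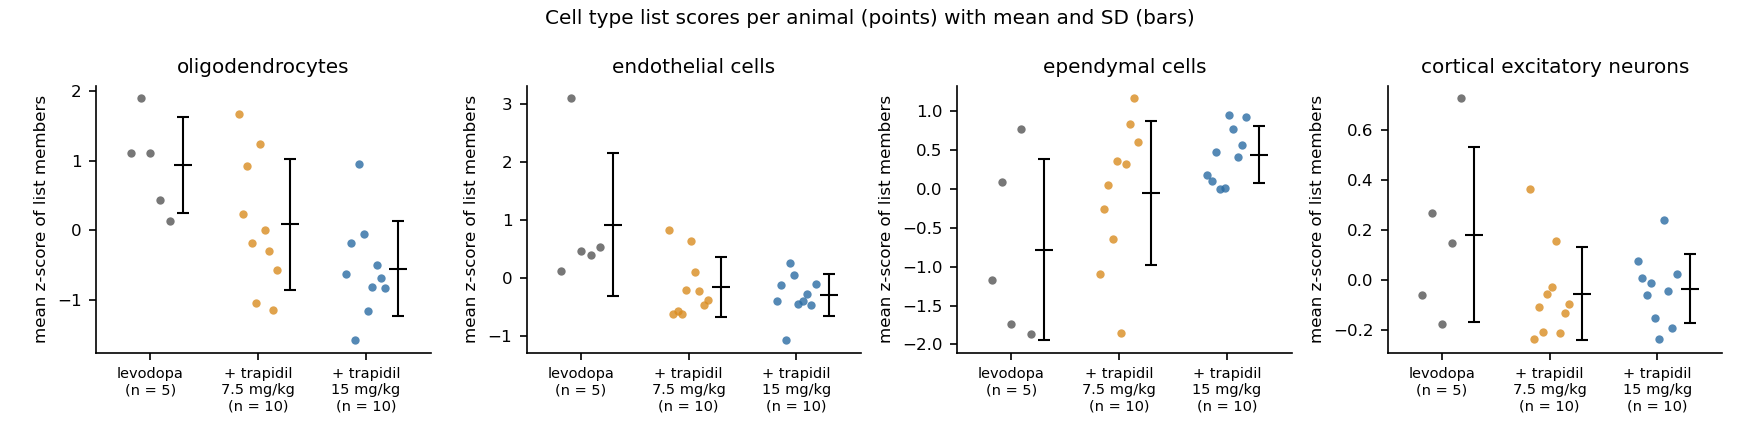
Mean z-score (vertical axes, no unit) of the oligodendrocyte, endothelial, ependymal and cortical excitatory neuron lists in each animal of the 3 arms (points), with the arm mean ± SD. The oligodendrocyte score averaged 0.93 with levodopa, 0.08 at 7.5 mg/kg and -0.55 at 15 mg/kg, and the ependymal score -0.78, -0.05 and 0.44.

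Endothelial markers were lower at 15 mg/kg in 15 of 15 members, with a median of -0.36. The transporters Slco1a4 (-0.47 ± 0.12; adjusted p = 0.0464) and Slc16a1 (-0.36 ± 0.09; adjusted p = 0.049) fell, each lower in 10 of 10 libraries. Adjusted over the list alone 13 members were lower, and the list gave adjusted p = 0.483 with an estimated correlation (10 of 10 libraries lower). Levodopa replicate 2 had the highest endothelial score, 3.09, against an arm mean of 0.91 ± 1.23 (SD, n = 5). Pdgfb, a ligand of the platelet-derived growth factor receptors, fell from 23.4 ± 4.95 CPM (SD, n = 5) to 16.9 ± 1.96 CPM (SD, n = 10), a log2 fold change of -0.46 ± 0.10 (adjusted p = 0.0282; 10 of 10 libraries). It was the 1 member of 16 on the list of these ligands, receptors and partners to pass, and 3 were lower when adjusted over the list alone. The receptors were at -0.17 ± 0.10 (Pdgfra) and -0.20 ± 0.11 (Pdgfrb) and did not pass. Pdgfb lost its call without levodopa replicate 2 (-0.33) or 3 (-0.48) and without the 15 mg/kg replicate 3 (-0.43) or 9 (-0.46). Slco1a4 lost its call without levodopa replicate 2 (-0.23) or 3 (-0.54), and Slc16a1 without levodopa replicate 1 (-0.35), 2 (-0.34) or 3 (-0.32). Both also lost it without any 1 of the 15 mg/kg replicates 1 to 3 and 5 to 10, with values between -0.48 and -0.45 for Slco1a4 and between -0.38 and -0.33 for Slc16a1.

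Among clock genes at 15 mg/kg, Per1 rose from 118 ± 19.2 CPM (SD, n = 5) to 160 ± 18 CPM (SD, n = 10), by 0.44 ± 0.09 on the log2 scale (adjusted p = 0.0217; 10 of 10 libraries). Per2 rose by 0.52 ± 0.10 (adjusted p = 0.0217) and Cry1 by 0.33 ± 0.08 (adjusted p = 0.0475), each higher in 10 of 10 libraries. These were the 3 of 19 clock genes to pass. There were 5 higher and 1 lower clock genes when adjusted over the list alone, and the list gave adjusted p = 0.483 with an estimated correlation (10 of 10 libraries higher). Per1 lost its call without levodopa replicate 2 (0.36) or 3 (0.41), as did Per2 (0.49 and 0.53). Cry1 lost its call without levodopa replicate 1 (0.35), 2 (0.31), 3 (0.34) or 5 (0.28), and without any 1 of the 15 mg/kg replicates 1 to 3, 5 and 7 to 10 (0.30 to 0.34).

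Single members of other lists also passed at 15 mg/kg. Rgs14 (0.56 ± 0.12; adjusted p = 0.0267) and Prkar1b, a regulatory subunit of protein kinase A (0.34 ± 0.08; adjusted p = 0.0437), rose in 10 of 10 libraries. The kainate receptor subunit Grik4 (-0.68 ± 0.14; adjusted p = 0.0217) and S100a10 (-0.72 ± 0.17; adjusted p = 0.0382) fell in 10 of 10 libraries. Without levodopa replicate 2 and without replicate 3 the calls of Rgs14 (0.50 and 0.57), Prkar1b (0.24 and 0.37), Grik4 (-0.63 and -0.66) and S100a10 (-0.61 and -0.79) ended. Further such libraries were the 15 mg/kg replicate 3 for Rgs14 (0.52), and 15 mg/kg replicates 1, 3, 5 to 7, 9 and 10 for Prkar1b (0.32 to 0.35). For S100a10 they were levodopa replicate 5 (-0.57) and the 15 mg/kg replicates 2, 3 and 5 to 10 (-0.74 to -0.67). Slc17a6, the vesicular glutamate transporter of thalamic and other subcortical neurons, and Ttr, an abundant choroid plexus transcript, fell, with log2 fold changes of -3.71 ± 0.77 and -5.11 ± 1.09 (both adjusted p = 0.0217; 10 of 10 libraries). Both rested on levodopa replicate 2, with 10.98 CPM of Slc17a6 and 23.4 CPM of Ttr against at most 1.00 and 0.528 CPM in the other levodopa animals. Without it the values were -1.52 and -0.79 and neither passed.

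By camera with an estimated correlation, 0 of 35 lists passed at 15 mg/kg, against 2 at an unadjusted p below 0.05, 17 with the preset correlation and 2 with fry. The gene count of 185 moved to 20 without levodopa replicate 2, 9 without levodopa replicate 3 and 894 without levodopa replicate 4. Without single 15 mg/kg animals it moved to 99 (replicate 1), 120 (replicate 2), 51 (replicate 3), 437 (replicate 4), 77 (replicate 6), 79 (replicate 7), 90 (replicate 8), 54 (replicate 9) and 86 (replicate 10). Aplnr, Dusp2, Ppp1r15a, Trim59 and Syt13 were the 5 genes of the 185 called in every one of these fits. With scores of 4 other brain regions and ventricular cell types in the design, 0 genes passed with edgeR, and Ppp1r15a was at -0.70. With the side of the first principal component as a block 0 genes passed as well, against 586 higher and 601 lower at an unadjusted p below 0.05. Ppp1r15a was then at -0.58 ± 0.16, Aplnr at -0.95, Dusp2 at -0.98 ± 0.38, Trim59 at -0.55 ± 0.14 and Syt13 at 0.35 ± 0.08. All 15 mg/kg animals lay on the high side, with levodopa replicate 4 as the 1 levodopa animal beside them. Within a side the 2 arms thus met only through that animal, so the loss of calls cannot tell a batch from an effect of trapidil. With the replicate number as a block 0 genes passed too, with Ppp1r15a at -0.87 ± 0.15 (adjusted p = 0.0864), Aplnr at -1.21 ± 0.21, Dusp2 at -1.63 ± 0.34, Trim59 at -0.62 ± 0.13 and Syt13 at 0.34 ± 0.07.

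The third comparison asked whether the doses differed from each other. Midn, whose protein promotes proteasomal degradation of nuclear proteins, was at 71.1 ± 7.87 CPM at 7.5 mg/kg and 97.4 ± 7.96 CPM at 15 mg/kg (SD, n = 10 each), a rise of 0.46 ± 0.06 on the log2 scale (edgeR adjusted p = 0.00158). Per1 rose from 118 ± 9.68 to 160 ± 18 CPM, by 0.44 ± 0.07 (adjusted p = 0.00512). Irs2, an adaptor of the insulin receptor, rose from 84.2 ± 14.7 to 126 ± 18 CPM, by 0.58 ± 0.09 (adjusted p = 0.00512). The zinc finger gene Zfp189 rose from 33.2 ± 3.49 to 49.4 ± 8.52 CPM, by 0.57 ± 0.10 (adjusted p = 0.0147). Each of these 4 genes was higher than the 7.5 mg/kg mean in 10 of 10 libraries of the 15 mg/kg arm, and all 4 were called whichever single library was left out. With levodopa alone Midn was at 81.4 ± 10.6, Irs2 at 102 ± 15.7 and Zfp189 at 35.8 ± 8.28 CPM (SD, n = 5), between the doses. These 3 genes were called against levodopa at neither dose, and Per1 at 15 mg/kg only. Zfp189 lost its call with the replicate number as a block (0.56) and with the 4 region scores in the design (0.53).

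**Figure D3:**
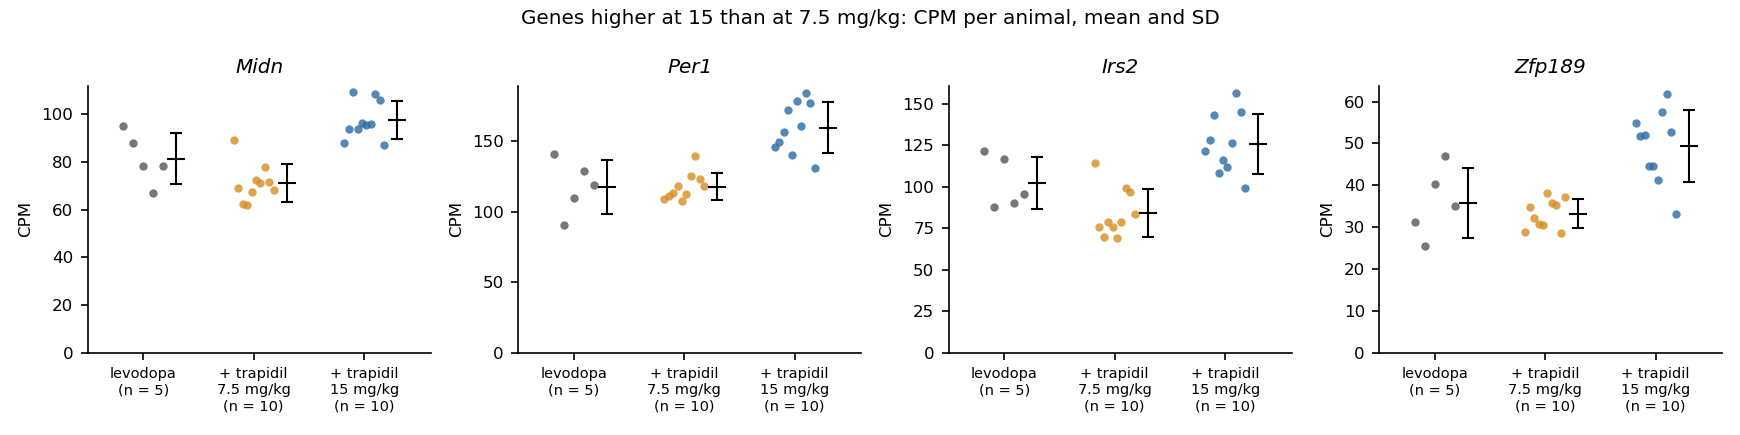
Library-scaled counts in CPM (vertical axes) of Midn, Per1, Irs2 and Zfp189 in each animal of the 3 arms (points), with the arm mean ± SD. Mean Midn was 81.4 CPM with levodopa alone, 71.1 CPM at 7.5 mg/kg and 97.4 CPM at 15 mg/kg.

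Feedback genes of the MAP kinase cascade had a median log2 fold change of 0.14 between the doses, with 15 of 17 members positive. The list passed, with adjusted p = 0.00704 with an estimated correlation and a list score above the 7.5 mg/kg mean in 10 of 10 libraries of the 15 mg/kg arm. Single members passed in 0 cases over all genes, and 7 were higher when adjusted over the list alone; Dusp5 had the smallest p (0.82 ± 0.20; adjusted p = 0.46; 9 of 10 libraries). Immediate early genes, which share Dusp4, Dusp6, Egr1 and Spry4 with that list, had a median of 0.22 with 25 of 35 positive. With edgeR 0 passed, 12 were higher when adjusted over the list alone, and the list gave adjusted p = 0.232 with an estimated correlation (9 of 10 libraries higher). Fosb, a gene whose products accumulate in the striatum under repeated levodopa, was at 34.3 ± 7.57 CPM at 7.5 mg/kg and 62.0 ± 16.1 CPM at 15 mg/kg (SD, n = 10 each), a log2 difference of 0.85 ± 0.17 that did not pass (adjusted p = 0.0727; 9 of 10 libraries). Glucocorticoid responsive genes had a median of 0.15 over 19 members, of which Per1 rose and 2 were higher when adjusted over the list alone (list adjusted p = 0.0989 with an estimated correlation; 8 of 10 libraries higher). Interneuron markers had a median of 0.11 and the same adjusted p = 0.0989 with an estimated correlation (9 of 10 libraries higher).

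Between the doses, 0 genes passed in the lower direction with edgeR. At an unadjusted p below 0.05 there were 302 lower and 211 higher genes, where chance would give 707.1 in all. DESeq2 called 0 and limma-voom 1 gene lower. Camera with an estimated correlation passed 1 of 35 lists, against 10 with the preset correlation and 1 with fry. The count of 4 genes became 8 without the 7.5 mg/kg replicate 1, and 9, all 4 among them, with the side of the first principal component as a block. The list count of 1 became 2 without the 7.5 mg/kg replicate 1, 3 without the 7.5 mg/kg replicate 6, and 2 without the 15 mg/kg replicate 3 or 6. It became 3 with that block.

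The fourth comparison set both trapidil doses (n = 20, each dose weighted equally) against levodopa alone (n = 5). Ppp1r15a fell by 0.96 ± 0.11 on the log2 scale (edgeR adjusted p = 3.1e-05; 20 of 20 libraries). Dusp2 (-1.76 ± 0.23; adjusted p = 0.000285) and Dusp6 (-0.86 ± 0.15; adjusted p = 0.00933) also fell in 20 of 20 libraries. Btg2 (-1.36 ± 0.22; adjusted p = 0.00466) and Jun (-1.19 ± 0.20; adjusted p = 0.00527) fell in 19 of 20. Aplnr (-0.92 ± 0.15; adjusted p = 0.00527) and Pdgfb (-0.49 ± 0.09; adjusted p = 0.016) fell in 20 of 20 libraries. Syt13 (0.28 ± 0.05; adjusted p = 0.0132), Per2 (0.48 ± 0.10; adjusted p = 0.025) and Banp (0.30 ± 0.06; adjusted p = 0.025) rose, each in 20 of 20 libraries. Pdgfb lost its call without levodopa replicate 2 (-0.35), Per2 without levodopa replicate 1 (0.47), 2 (0.45) or 3 (0.49), and Banp without levodopa replicate 2 (0.30) or 3 (0.30). In all 114 genes passed, 94 lower and 20 higher. Of these, 18 of the higher and 81 of the lower genes were also called at 15 mg/kg, a comparison made on the same libraries.

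Further lower genes were Trim59 (-0.53 ± 0.09), Tspan2 (-0.54 ± 0.10), Stard9 (-0.53 ± 0.10) and Rrbp1 (-0.46 ± 0.09), each in 20 of 20 libraries with adjusted p from 0.00933 to 0.0158. Without levodopa replicate 2 the calls of Rrbp1 (-0.25), Tspan2 (-0.43) and Stard9 (-0.43) ended, and without levodopa replicate 3 those of Tspan2 (-0.50) and Stard9 (-0.49). Further higher genes were Slc9a5, Atp6ap1l, Wdr19, Fam216a, Mapkbp1, Ripor2 and Car12, with log2 fold changes from 0.19 to 0.46 and adjusted p from 0.0396 to 0.0479, each in at least 19 of 20 libraries. All 7 lost their calls without levodopa replicate 1, 2 or 3 (0.18 to 0.54), and each lost it in 15 to 20 of the 25 fits that left out 1 library. Of the 35 immediate early genes 10 fell, including Arc (-1.35 ± 0.29; adjusted p = 0.0301; 19 of 20 libraries) and Csrnp1 (-0.60 ± 0.12; adjusted p = 0.0173; 19 of 20 libraries). Adjusted over the list alone 19 were lower and 2 higher, and the list median of -0.47 had adjusted p = 0.389 with an estimated correlation (19 of 20 libraries lower). Arc lost its call without levodopa replicate 1 (-1.27), 2 (-1.34) or 3 (-1.19).

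With both doses against levodopa, oligodendrocyte genes had a median of -0.44 with 19 of 19 members negative. Opalin fell (-0.65 ± 0.14; adjusted p = 0.0301; 20 of 20 libraries), 17 were lower when adjusted over the list alone, and the list had adjusted p = 0.389 with an estimated correlation (17 of 20 libraries lower). Opalin lost its call without levodopa replicate 2 (-0.52) or 3 (-0.64). Endothelial markers had a median of -0.36, and Slc16a1 (-0.37 ± 0.08; adjusted p = 0.0406) and Slco1a4 (-0.44 ± 0.11; adjusted p = 0.0486) fell, each in 20 of 20 libraries. Adjusted over the list alone 13 members were lower, and the list had adjusted p = 0.389 with an estimated correlation (20 of 20 libraries lower). This tally too leaned on the high score of levodopa replicate 2. Slco1a4 and Slc16a1 lost their calls without levodopa replicate 1 (-0.50 and -0.36), 2 (-0.20 and -0.35) or 3 (-0.51 and -0.33). Slco1a4 also lost it without the 7.5 mg/kg replicates 2 to 5 and 7 to 10 (-0.45 to -0.42) and the 15 mg/kg replicates 1 to 3 and 5 to 10 (-0.45 to -0.43), left out 1 at a time. For Slc16a1 these were the 7.5 mg/kg replicates 4, 5 and 7 to 10 (-0.37 to -0.36) and the 15 mg/kg replicates 3, 6, 7 and 9 (-0.37 to -0.36). Slc30a3, the zinc transporter of cortical glutamatergic terminals, fell by 1.41 ± 0.33 (adjusted p = 0.0425; 20 of 20 libraries). It was the 1 member of 13 cortical excitatory markers to pass, and 2 were lower when adjusted over the list alone. Its call ended without levodopa replicate 1 (-1.45), 2 (-1.37) or 5 (-1.02), without the 7.5 mg/kg replicate 2, 4, 5, 7, 8, 9 or 10 (-1.44 to -1.36), and without the 15 mg/kg replicate 1, 5, 7, 8, 9 or 10 (-1.42 to -1.36). Prkar1b rose (0.32 ± 0.08) and Akap12, an anchor of protein kinase A, fell (-0.42 ± 0.10), both with adjusted p = 0.0486 and in 20 and 19 of 20 libraries. They lost their calls without levodopa replicate 1 (0.36 and -0.46), 2 (0.22 and -0.26) or 3 (0.35 and -0.46), and Akap12 also without levodopa replicate 5 (-0.42). Both lost them without any 1 of the 7.5 mg/kg replicates 2 to 5 and 7 to 10 (0.31 to 0.33 and -0.43 to -0.41). The same held for the 15 mg/kg replicates 1 to 3, 5 to 7, 9 and 10 with Prkar1b (0.31 to 0.33) and 1 to 3 and 5 to 10 with Akap12 (-0.43 to -0.41).

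By camera with an estimated correlation, 0 of 35 lists passed for both doses together, against 4 at an unadjusted p below 0.05, 15 with the preset correlation and 0 with fry. The count of 114 genes moved to 49, 19, 22 and 517 without levodopa replicate 1, 2, 3 and 4. It moved to 624 and 297 without the 7.5 mg/kg replicates 1 and 6, and to between 44 and 51 without any 1 of the 7.5 mg/kg replicates 2, 4, 5, 7, 8, 9 and 10. It moved to 190 without the 15 mg/kg replicate 4, and to between 45 and 69 without any 1 of the other 15 mg/kg replicates. Aplnr, Btg2, Csrnp1, Dusp2, Dusp6, Jun, Ppp1r15a, Trim59 and Syt13 were the 9 genes of the 114 called in every one of these fits. Slc17a6 (-3.29 ± 0.62; adjusted p = 0.0158; 19 of 20 libraries) and Ttr (-4.02 ± 0.82; adjusted p = 0.0252; 17 of 20 libraries) again rested on levodopa replicate 2, and without it they were at -1.10 and 0.31 and neither passed. With the 4 region and ventricular scores in the design, 1 gene passed. The replicate number as a block, which did not pair the animals, ended most calls too, keeping 6 of the 79 named calls over all comparisons. With the side of the first principal component as a block 0 genes passed with edgeR, against 714 higher and 756 lower at an unadjusted p below 0.05, and Ppp1r15a was at -0.62 ± 0.14 and Jun at -0.55 ± 0.27.

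Transcripts of the dopamine receptors and striatal neuropeptides, which mark the direct and indirect output pathways, passed in none of the 4 comparisons. Against levodopa, Drd1 was at 0.09 ± 0.13 (7.5 mg/kg) and 0.10 ± 0.13 (15 mg/kg) on the log2 scale, and Drd2 at 0.14 ± 0.09 and 0.09 ± 0.09. Drd3 was at 0.45 ± 0.48 and 0.83 ± 0.47, Tac1 at 0.02 ± 0.11 and 0.18 ± 0.11, and Penk at 0.03 ± 0.14 and 0.01 ± 0.14. Pdyn, the dynorphin precursor that levodopa raises in lesioned striatum, was at 292 ± 130 CPM (SD, n = 5), 294 ± 104 CPM and 237 ± 35.1 CPM (SD, n = 10 each), with log2 fold changes of 0.01 ± 0.21 and -0.30 ± 0.21. Trh (-0.17 ± 0.21 and -0.44 ± 0.21), Nptx2 (-0.06 ± 0.15 and 0.04 ± 0.15), Homer1 (0.28 ± 0.14 and 0.39 ± 0.14), Pdgfa (-0.02 ± 0.10 and -0.03 ± 0.10) and Tbxa2r, the thromboxane receptor (0.06 ± 0.20 and 0.12 ± 0.20), did not pass either. The list of genes associated with levodopa and dyskinesia had medians of 0.03 and 0.16 over 21 members, of which Arc fell at 15 mg/kg and was the 1 lower member when adjusted over the list alone at each dose. Direct pathway markers had medians of 0.08 and 0.09 over 12 members, indirect pathway markers 0.07 and 0.08 over 12, and markers of all spiny projection neurons 0.08 and 0.10 over 22. With edgeR 0 of these members passed, and adjusted over the list alone 2 direct pathway markers were higher at 15 mg/kg. The smallest adjusted p of these 4 lists against levodopa was 0.483 with an estimated correlation, at 15 mg/kg, where the scores were higher in 8 to 10 of 10 libraries. That tally leans on a levodopa mean pulled down by its lowest animal. This animal scored -2.91 for all spiny projection neurons (arm mean -0.43 ± 1.39; SD, n = 5). The lowest direct and indirect pathway scores were -2.35 (mean -0.40) and -2.43 (mean -0.27).

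Of the lists tied to the known actions of trapidil, none passed against levodopa. Phosphodiesterases had medians of 0.14 and 0.16 over 18 members (adjusted p = 0.316 and 0.483 with an estimated correlation; higher in 9 and 10 of 10 libraries). With edgeR 0 passed at either dose, 4 were higher at 15 mg/kg when adjusted over the list alone, and Pde4a came nearest at 0.22 ± 0.07 (adjusted p = 0.0866; 10 of 10 libraries). Genes of cAMP and protein kinase A signalling had medians of 0.07 and 0.08 over 26 members, with 1 higher and 2 lower at 7.5 mg/kg and 3 higher and 1 lower at 15 mg/kg when adjusted over the list alone. The prostanoid and thromboxane system had medians of 0.01 and -0.04 over 13 members, and Ptgds, the prostaglandin D synthase, was at -0.65 ± 0.17 at 15 mg/kg (adjusted p = 0.0507; 10 of 10 libraries). The list of platelet-derived growth factor ligands and receptors had medians of -0.12 and -0.04.

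**Figure D4:**
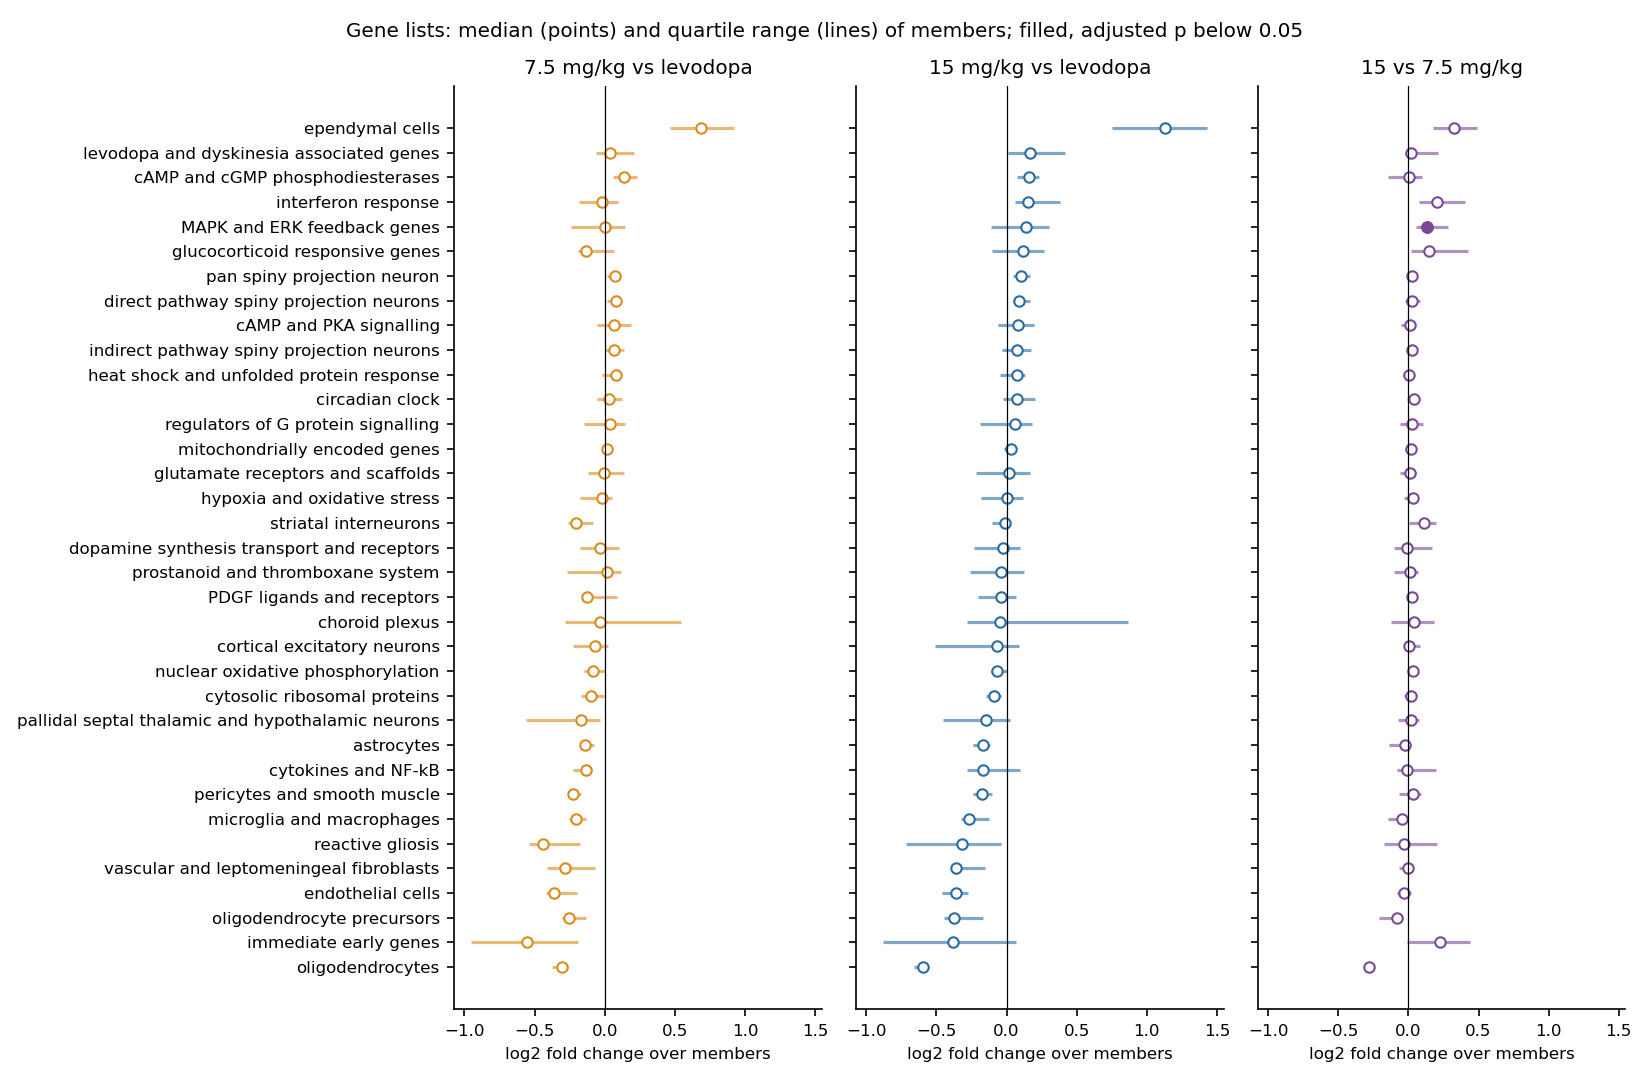
Median and quartile range of the members' log2 fold changes (horizontal axis) for 35 gene lists in 3 comparisons: 7.5 mg/kg against levodopa, 15 mg/kg against levodopa, and 15 against 7.5 mg/kg. Filled points mark lists with an adjusted p below 0.05, which was the MAP kinase feedback list between the doses, with a median of 0.14.

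Among the other cell type lists, the medians at 7.5 and 15 mg/kg against levodopa were -0.14 and -0.17 for 18 astrocyte markers, -0.21 and -0.26 for 17 microglia and macrophage markers. They were -0.23 and -0.17 for 17 pericyte and smooth muscle markers, and -0.28 and -0.36 for 15 fibroblast markers. In the order of these 4 lists, the highest levodopa animal scored 2.72, 2.29, 2.51 and 2.22, against arm means of 0.51, 0.50, 0.48 and 0.46 (n = 5). The levodopa level of each list therefore leaned on 1 animal. Reactive gliosis genes had medians of -0.44 and -0.32 over 17 members, of which S100a10 fell at 15 mg/kg and 3 were lower there when adjusted over the list alone. Interneuron markers were at -0.01 at 15 mg/kg, and precursor markers of oligodendrocytes at -0.25 at 7.5 mg/kg, where oligodendrocyte markers were at -0.30 and ependymal markers at 0.69. Cortical excitatory markers had medians of -0.07 and -0.07 over 13 members, neurons of pallidum, septum, thalamus and hypothalamus -0.17 and -0.15 over 13, and choroid plexus -0.03 and -0.04 over 7. Blood cell genes, with 4 tested members and no list test, had medians of 0.09 and -0.10.

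Among the pathway lists, medians at 7.5 and 15 mg/kg were -0.03 and -0.02 for 15 genes of dopamine synthesis, transport and receptors, 0.04 and 0.06 for 15 regulators of G protein signalling, and 0.00 and 0.02 for 28 glutamate receptor and scaffold genes. They were 0.00 and 0.14 for 17 MAP kinase feedback genes, -0.13 and -0.17 for 14 cytokine and NF-kB genes, -0.02 and 0.15 for 24 interferon response genes, and -0.14 and 0.12 for 19 glucocorticoid responsive genes. Clock genes were at 0.03 and 0.07, 24 heat shock and unfolded protein response genes at 0.08 and 0.07, and 18 hypoxia and oxidative stress genes at -0.02 and 0.00. Nuclear genes of oxidative phosphorylation were at -0.08 and -0.07 over 77 members, mitochondrially encoded genes at 0.02 and 0.03 over 13, and cytosolic ribosomal proteins at -0.10 and -0.09 over 68. The median, the mean and the direction of the list test differed in sign for 6 of the 35 lists at 7.5 mg/kg, 3 at 15 mg/kg, 10 between the doses and 4 for both doses. Among them were choroid plexus, with negative means (-0.20 at 7.5 mg/kg and -0.40 at 15 mg/kg) and an upward test, and MAP kinase feedback genes at 7.5 mg/kg, with a mean of -0.16 and a downward test beside a median of 0.00.

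The responses to the 2 doses were compared across 14140 genes, which are not independent replicates. Their log2 fold changes against levodopa correlated with r = 0.852 and a covariance of 0.0610, and 83.5% of genes had the same sign. Ppp1r15a (-0.96 and -0.95), Btg2 (-1.33 and -1.39), Arc (-1.34 and -1.35) and Pdgfb (-0.51 and -0.46) had close values at both doses. Both comparisons used the same 5 levodopa libraries, and in 100 simulated sets with no effect those shared controls alone gave a mean correlation of 0.673 (range 0.640 to 0.697), a covariance of 0.0235, 73.2% of genes with the same sign and 0 shared calls. The covariance exceeded the simulated one by 0.0376. The simulated genes were drawn independently of each other and without a structure of the samples, which the real libraries have. The simulated values may therefore understate what shared controls give, and the excess cannot be read as a shared response. With the levodopa libraries split into 2 for one dose and 3 for the other, 20 splits gave a median correlation of 0.285 (range 0.0291 to 0.435) and a median covariance of 0.0328 (range 0.00491 to 0.0506).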

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

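The tests of library depth, of a lower share of oligodendrocytes and of less vessel, the fits with 4 region scores and the fits with the side of the first principal component as a block, were chosen only after the data had been seen. Among 204 groups of single values (66 genes, the total count and the mitochondrial share, each in 3 arms), 19 values stood far from the rest of their arm by Dixon's test at the 95% level, where chance marks about 1 in 20 groups, or 10.2 here; genes are not independent. Levodopa replicate 2 was highest in its arm for Aplnr (7.65 CPM, next 4.78), Pdgfb (31.9 CPM, next 22.8), Pdgfra (126 CPM, next 75.9), Rrbp1 (134 CPM, next 83.2) and Slco1a4 (137 CPM, next 75.1), and lowest for Drd1 (109 CPM, next 219), Homer1 (36.9 CPM, next 72.3) and Rgs14 (62.7 CPM, next 77.9). Levodopa replicate 4 was lowest for Arc (170.7 CPM, next 506). The 7.5 mg/kg replicate 1 had the lowest total count of its arm, 1.084e+07 against 1.55e+07 in the next library, the highest Btg2 (31.7 CPM, next 12.03) and the lowest Rdh10 (16.1 CPM, next 20.8) and Tac1 (117 CPM, next 159), and the 7.5 mg/kg replicate 6 the highest Akap12 (29.4 CPM, next 21.7). At 15 mg/kg, Cnp was highest in replicate 4 (844 CPM, next 609), Drd1 lowest in replicate 10 (178 CPM, next 213), Penk lowest in replicate 6 (2664 CPM, next 4004), Slco1a4 lowest in replicate 3 (52.7 CPM, next 59.3), and Slc17a6 was at 0 in replicate 10 (next 0.134 CPM).

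The effect against levodopa differed between the doses, by the direct contrast of the doses, for Midn (15 minus 7.5 mg/kg, 0.46 on the log2 scale), Per1 (0.44), Irs2 (0.58) and Zfp189 (0.57). Midn, Irs2 and Zfp189 were called against levodopa at neither dose, and their levodopa means lay between those of the doses.

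Immediate early genes had a median log2 fold change of -0.47 over 35 members with both doses against levodopa. The median total counts of trapidil and levodopa libraries differed by -2.15%, within the 10% bound set for library depth, which argues against depth. Without levodopa replicate 3 the median log2 fold change was nearest 0, at -0.36 (95% interval -0.62 to -0.20). With the 4 region scores in the design it was -0.16 (-0.38 to -0.07). The first of these medians stayed beyond the bound set for these tests and the second lay nearer 0 than it, but both intervals reach to either side. The intervals are over genes that are not independent and do not measure the spread between animals. A single levodopa animal and other brain regions in the dissections therefore cannot be told apart from an effect of trapidil on these genes. With the side of the first principal component as a block the median was -0.032 (-0.22 to 0.11), as a batch along that component would give. The labels give no dissection or library batch. The component was taken from the same data and holds 4 of the 5 levodopa animals on its low side, so an effect of trapidil that moved it would give this too, and both stay open.

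Oligodendrocyte genes had a median of -0.59 at 15 mg/kg against levodopa. Without levodopa replicate 2 it was still -0.49 (95% interval -0.53 to -0.46), which argues against a single levodopa animal as the whole source. With the 4 region scores it was -0.061 (-0.12 to 0.03), as a different mix of regions or ventricular wall in the dissections would give. The ependymal score, 1 of the 4, itself differed between the arms (mean -0.78 with levodopa and 0.44 at 15 mg/kg). The fit with these scores therefore cannot tell a region mix from an effect of trapidil. It is also not independent of the first principal component, which had cilia genes at its high end. The members moved alike, 100% of 19 negative with quartiles of -0.66 and -0.55, as a lower share of these cells in the samples would give. With the side of the first principal component as a block the median was -0.17 (-0.24 to -0.085), as a batch along it would give. No 15 mg/kg animal lay on its low side, and levodopa replicate 4 was the 1 levodopa animal on its high side. That fit therefore cannot tell a batch from an effect of trapidil. Region mix, such a batch and an effect of trapidil on these cells all stay open, and the data hold no record of the dissections to weigh them further.

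Endothelial genes had a median of -0.36 with both doses against levodopa. Pericyte and smooth muscle markers were at -0.19, and the difference of the medians was -0.16 (95% interval -0.23 to -0.02), or -0.13 (-0.23 to -0.02) without levodopa replicate 2. Without that animal the pericyte and smooth muscle median itself was -0.045, so most of its fall rested on that animal. Vascular and leptomeningeal fibroblast markers, however, were at -0.33, a difference of -0.030 (-0.26 to 0.15). This wider interval includes the difference from pericyte markers, so the 2 comparisons do not contradict each other. The fibroblast comparison was not run without levodopa replicate 2. Less vessel in the samples stays open. The ependymal score, 1 of the 4 region scores, itself differed between the arms. With those scores the endothelial median was -0.093 (-0.16 to -0.08), as a different mix of regions or an effect of trapidil could give. Without levodopa replicate 2 it was -0.18 (-0.25 to -0.02), an interval that reaches to either side of the bound set for it, so that this 1 animal could account for part of it or for most of it. With the side of the first principal component as a block it was -0.17 (-0.25 to -0.13), an interval that also reaches to either side of the bound. A batch along that component cannot be told apart from an effect of trapidil on endothelial genes, which stays open.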

How the results depend on the processing

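Leaving out 2 doubted libraries together, the fits with 4 region scores and those with the side of the first principal component as a block (first component block) were chosen after seeing the data. The dose contrast was the most stable count: Midn, Per1 and Irs2 were called under every alternative run, and Zfp189 under all but the replicate block (0.56) and the 4 region scores (0.53). Counts of called genes against levodopa at 7.5 mg/kg (4), 15 mg/kg (185) and both doses (114) stayed within 1.5 times under RLE and upper-quartile normalization and a filter of 1 CPM in 5 libraries, and all 79 named calls were kept under RLE. In simulated data at 15 mg/kg, with genes drawn independently, 49 of 67 changes of 1.5-fold and 64 of 65 of 4-fold were recovered.

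In the order 7.5 mg/kg, 15 mg/kg and both doses against levodopa, the count was 11, 862 and 493 at an adjusted p below 0.10, 53, 649 and 427 with DESeq2, and 102, 715 and 563 with limma-voom. It was 27, 76 and 65 without the 2 doubted libraries, 1, 0 and 1 with the 4 region scores, 0, 0 and 0 with the first component block and 1, 8 and 4 with the cortical score. Of the 185 genes, 185 were also called by DESeq2, 174 by limma-voom, 57 without the doubted libraries and 12 with surrogate variables. Other counts that moved were 37 and 40 with 2 surrogate variables at 7.5 and 15 mg/kg, 1 and 448 with only the groups compared in the fit, and 7 at 7.5 mg/kg with no low-count filter. Between the doses the count of 4 became 10 with 2 surrogate variables, 13 with limma-voom and 9 without the doubted libraries or with the first component block. Fewer libraries in the fit, a looser threshold and fewer genes removed are part of these settings; otherwise the cause was not tested.

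With the replicate number as a block (replicate block) the counts were 0 at 7.5 mg/kg, 0 at 15 mg/kg and 6 for both doses, and 4 between the doses. Ppp1r15a at 7.5 mg/kg lost its call at -0.87, against -0.96 without the block. The numbers did not pair the animals: the mean correlation of same-numbered libraries was -0.0747, -0.0288 and 0.0302 over the 3 pairs of arms, pairs over 0.1 numbered 1 of 5, 1 of 5 and 4 of 10, and 0 of 5, 1 of 5 and 0 of 10 libraries matched best with their own number.

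Leaving out 1 library gave 1 to 70 genes at 7.5 mg/kg, 9 to 894 at 15 mg/kg, 19 to 624 for both doses and 4 to 8 between the doses. Lists called were 0 to 2 at 7.5 mg/kg and 1 to 3 between the doses, and 0 in each such fit at 15 mg/kg and for both doses. Of 75 named calls, 21 were kept without levodopa replicate 2, 22 without replicate 3 and 75 without replicate 4.

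With the preset correlation, 17, 17, 10 and 15 lists passed at 7.5 mg/kg, at 15 mg/kg, between the doses and for both doses, against 0, 0, 1 and 0 with the estimated one. Fry passed 2 and 2 lists against levodopa. Without the doubted libraries 1 list passed at 7.5 mg/kg, the immediate early genes (adjusted p = 0.0102), and 2 between the doses; with 2 surrogate variables, the 4 region scores or the first component block 3 passed between the doses. The correlation of the responses to the doses fell from 0.852 to 0.285 with split levodopa libraries, which removed the sharing but also left 2 or 3 controls per dose; these 2 causes were not separated. Ttr for both doses turned from -4.02 to 0.15 with 2 surrogate variables, 0.30 with the 4 region scores and 0.31 without levodopa replicate 2, the animal with most of its counts, and ranged from -4.34 to 0.31 over the 21 left-out libraries with which it was still tested.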

Other observations

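Cfap44, Cfap65, RT1-Db1 and Cbln1, chosen after their values were seen, had the top loadings on the first principal component of the libraries, which took 28.9% of the variance. The cilia genes Cfap44 and Cfap65 stood at its high end, and the MHC class II gene RT1-Db1 and the synaptic organiser Cbln1 at its low end; no gene group was tested on it. Levodopa replicates 1, 2, 3 and 5 lay at -31.8, -19.8, -33.6 and -32.8, near the 7.5 mg/kg replicates 1 and 6 at -38.4 and -42.5, while levodopa replicate 4 lay at 14.0 and the 15 mg/kg animals between -7.18 and 22.8. Levodopa replicate 4 also had low Arc (170.7 CPM) and Btg2 (13.5 CPM), and the 7.5 mg/kg replicate 1 high Arc (597 CPM) and Btg2 (31.7 CPM), while the 7.5 mg/kg replicate 6 had low Arc (134 CPM) and Btg2 (9.25 CPM) in spite of its place. Whether dissections or library preparations followed this component is not recorded in the labels. Counts against levodopa therefore mix the arms with it, and with its side as a block they were 0 genes at 7.5 mg/kg, at 15 mg/kg and for both doses. The whole 15 mg/kg arm shared a side with 1 levodopa animal, replicate 4, so losing calls there says little about a batch. The second component (11.7%) was led by Ttr and Slc17a6 and set levodopa replicate 2 apart at -54.0, and the third (8.08%) set the 7.5 mg/kg replicate 1 apart at -47.2.

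Real and random regroupings of the libraries were compared over 100 splits per contrast. At 15 mg/kg against levodopa 1 of the 100 gave as many genes as the real 185, the real one, and the highest other gave 10. This is below the 5 set beforehand, so a random split seldom gave as many. The real count fell to 9 without levodopa replicate 3, however. The splits cannot exclude that a structure of the samples fell along the arms by chance. Between the doses 1 of the 100, the real one, gave as many as the real 4, the highest other giving 0, so a random split seldom gave as many here either. For both doses against levodopa 3 of the 100 gave as many as the real 114, fewer than the 5 set beforehand. With 100 splits 3 can hardly be told from 5, so chance is not excluded. The highest others gave 1103 and 1012, several times the real count, which points to a structure of the samples other than the arms. At 7.5 mg/kg against levodopa 5 of the 100 gave as many as the real 4 and the highest other gave 1248, so chance cannot be excluded, and that split too points to a structure of the samples.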
